A study of Mus musculus with 8 samples.

How the data were processed

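RNA from bone marrow-derived macrophages of mice was sequenced in 8 libraries, 2 in each of 4 groups: WT without LPS (WT_con), ELF1 KO without LPS (KO_con), WT with the M1 label (WT_M1) and ELF1 KO with the M1 label (KO_M1). The M1 label was read as the arm given lipopolysaccharide (LPS) for 6 h, because LPS is the one stimulus named in the study's design. The labels do not say whether libraries of the same group come from separate animals, so the p-values measure the spread between these libraries alone.

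The authors deposited 1 table of FPKM, a read count divided by gene length and library size, for 54532 genes, with gene positions and, in bases, the deposited gene length, whose unit is not FPKM. The authors' processing notes name the mm10 build and DESeq2, with no version or role. The aligner, the read counter and the annotation release are not given in the sources used here. Gene positions were taken from the deposited table, and GENCODE M21 gave the transcript sequences of mt-Nd3 and its nuclear copy Gm28438.

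FPKM times gene length was a whole multiple of 1 step per library, within 0.001 of a whole number for 100% of the values above 0. Reads per gene were rebuilt from these steps and summed to 15753259 to 18058974 per library. The library size implied by the deposited FPKM differed from that sum: their ratio was 1.21 to 1.28 without LPS, 0.784 to 0.797 in WT_M1 and 0.914 to 0.925 in KO_M1. Divided by the geometric mean of the rebuilt totals instead, the implied sizes were 0.757 to 1.31. These followed the median-of-ratios factors computed from the rebuilt reads, 0.740 to 1.29, and the scaling of the deposited values is inferred from that. A count of 0 allows 3 reads, or 0.166 to 0.190 CPM (reads per 1000000 of the rebuilt total), for counting error alone. Of the genes, 28813 were at 0 in all 8 libraries, and 103 entries carried a symbol used more than once.

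Differences were tested with limma-trend 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 4 groups in 1 model. The test took the 11887 genes at an FPKM of at least 1 in at least 2 libraries. Benjamini-Hochberg adjustment was made within each comparison, and a gene passed at an adjusted p under 0.05. The model had 4 residual degrees of freedom and a prior of 2.74. The comparisons were LPS against no LPS in WT and in KO, KO against WT without and with LPS, and the interaction, which is the LPS change in KO less that in WT. Changes are given as log2 ± SE, and FPKM as mean ± SD with n = 2 per group.

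Before the data were examined, 41 gene lists with 791 genes (782 in the table) were written down, along with the comparisons, the groups and 22 alternatives. The 33 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. All p-values of limma, camera and fry are two-sided. No list passed with an estimated correlation in any of the 5 comparisons, so each list's call rests on the preset one.

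The named genes also followed a rule fixed in advance. It takes Elf1, its neighbours and the housekeeping genes Actb, Gapdh, Hprt, Tbp and B2m. In each comparison it takes the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05 and a mean FPKM of at least 5 in the higher group, without predicted or clone names. Outside the interaction their libraries must not overlap between groups. From each list described it takes the members with the largest changes among those that passed, or among those tested where none passed; no member of the apoptosis list is named for KO against WT with LPS. The genes Tnf, Il6, Il10, Mrc1, Cx3cr1, Fcgr4, Csf1r, Mertk, Elk3, Fli1, Tpi1 and Ldha in the genotype comparisons and the interaction, and Gm28438, were chosen after their values were seen.

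The alternatives were other pseudocounts (0.1 and 5), an FPKM minimum of 5 or none, TPM, median-of-ratios and quantile scaling, limma without a trend or with robust moderation, replicate blocks, models with only the libraries compared, leaving out each library in turn, fry and the estimated correlation. After the data were seen 4 were added: voom on the rebuilt reads, scaling to total reads, leaving out genes under 300 bases and leaving out list members that stand on another list. As deposited, the median log2 change of all tested genes was 0.04 for LPS in WT, 0.02 for LPS in KO, -0.0024 for KO against WT without LPS, -0.02 with LPS and -0.01 for the interaction. Under TPM scaling, where 15752 genes were tested, these medians were -0.51, -0.42, 0.07, 0.15 and 0.09. Under total-read scaling, with 12137 genes, they were -0.48, -0.37, 0.05, 0.14 and 0.09, and under quantile normalization they were -0.13, -0.11, 0.0067, 0.02 and 0.02.

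The procedure was tested on simulated data with 200 changed genes, built without any KO against WT change in the libraries without LPS. For KO against WT with LPS it recovered 59.7, 95.5 and 97.0% of changes of 1.5, 2 and 4 times, with 14 false calls. For the interaction it recovered 26.9, 76.1 and 95.5%, with 8 false calls, and KO against WT without LPS gave 0. Many changes of 1.5 times did not pass in that setting. The simulation tested 11215 genes without any LPS change and drew the changed genes above a minimum level. It also added counting noise to a spread that already held it. Its 200 changed genes were a smaller share than the 3438 genes called in KO against WT with LPS and the 1900 in the interaction. The recovery rates therefore need not hold for the data. Matching lists of random genes, bootstrap intervals and exact Clopper-Pearson intervals used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Count models of other tools, planned for a table of raw counts alone, were not run on the rebuilt reads, and voom was. Exons, splice junctions and sequence variants were not analysed here.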

Results

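Gene expression was measured by RNA sequencing in 8 libraries of mouse bone marrow-derived macrophages, which are macrophages grown from marrow progenitors. The libraries formed 4 groups of 2: WT and ELF1 KO cells, each without LPS and with LPS for 6 h. LPS, a component of the outer membrane of Gram-negative bacteria, is sensed by the receptor TLR4. Elf1 is a transcription factor of the ETS family. A library is named here by its genotype label, con (no LPS) or M1 (LPS), and its replicate number. The rebuilt reads numbered 17297543 to 18058974 per library without LPS and 15753259 to 17133646 with LPS. In the libraries without LPS 19823 to 20168 genes had a value above 0, and 18626 to 19143 had one with LPS. The 10 most abundant genes took 12.5 to 13.3% of the reads without LPS and 8.14 to 8.49% with it. The median absolute log2 difference between replicates ran from 0.0720 in KO_con to 0.105 in WT_con. In a principal component analysis the first component held 89.6% of the variance and parted the libraries by LPS. The second held 4.12% and parted them by genotype label.

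Elf1, the gene named in the KO label (ENSMUSG00000036461, mm10 chromosome 14, 79481194 to 79582494), was read in all 8 libraries, with 1618 to 2515 reads each. Its level was 13.2 ± 1.22 FPKM in WT_con, 16.5 ± 0.567 in KO_con, 22.1 ± 0.397 in WT_M1 and 17.2 ± 1.04 in KO_M1 (mean ± SD, n = 2). Without LPS the KO against WT difference was 0.30 ± 0.07 (adjusted p = 0.0699), which did not pass, although it passed under TPM, quantile and total-read scaling at 0.36 to 0.39 (adjusted p = 0.0418 to 0.0473). It also passed with voom at 0.32 (adjusted p = 0.00378), with an FPKM minimum of 5 (adjusted p = 0.0465) and without WT_con 2 at 0.38 (adjusted p = 0.0469). With LPS Elf1 fell by 0.35 ± 0.07 (adjusted p = 0.0133) in KO, a call that ended under TPM, quantile and total-read scaling at -0.14 to -0.20 (adjusted p = 0.110 to 0.205). It also ended without WT_M1 1, WT_M1 2 or KO_M1 1 (adjusted p = 0.0507 to 0.0728). LPS raised Elf1 in WT by 0.70 ± 0.07 (adjusted p = 1.15e-04), but by only 0.14 and 0.11 under TPM and total-read scaling, where it did not pass (adjusted p = 0.140 and 0.231). In KO the LPS change was 0.06 ± 0.07 (adjusted p = 0.501), and it turned to -0.29 to -0.41 under TPM, quantile and total-read scaling (adjusted p = 0.0028 to 0.0134). The difference between the LPS responses passed (-0.64 ± 0.10, adjusted p = 0.00891) and kept its call under those 3 scalings. A total per gene cannot show whether part of the transcript is missing.

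The neighbours of Elf1 were compared for the same label. Wbp4 (chromosome 14, 79459937 to 79481520), which overlaps Elf1 by 327 bases, was 0.07 ± 0.08 (adjusted p = 0.696) in KO against WT without LPS. With LPS it fell by 0.34 ± 0.08 (adjusted p = 0.0216), and its interaction was -0.41 ± 0.11 (adjusted p = 0.0582). The Wbp4 fall ended without WT_M1 1, KO_M1 1 or KO_M1 2 (adjusted p = 0.0635 to 0.102) and under TPM and total-read scaling (adjusted p = 0.222 and 0.220). Sugt1 (79587691 to 79635196) did not pass at -0.07 ± 0.06 without LPS, -0.15 ± 0.06 with LPS and -0.08 ± 0.09 in the interaction. Among housekeeping genes, Actb (cytoskeletal actin) rose with LPS by 1.78 ± 0.06 in WT and 1.57 ± 0.06 in KO, and B2m (the light chain of MHC class I) by 1.34 ± 0.12 and 1.20 ± 0.12. Hprt (purine salvage) fell by 0.27 ± 0.07 in WT and fell by 0.30 ± 0.07 in KO. Its call ended in WT without WT_con 2 or WT_M1 1 (adjusted p = 0.0657 to 0.0702) and in KO without KO_con 2 (adjusted p = 0.0533). In KO against WT Actb fell by 0.29 ± 0.06 without LPS and fell by 0.50 ± 0.06 with LPS, and B2m was -0.31 ± 0.12 without LPS (not passing) and fell by 0.45 ± 0.12 with LPS. The Actb call without LPS ended when any single con or WT_M1 library was left out (adjusted p = 0.0829 to 0.247) and under TPM, quantile and total-read scaling (adjusted p = 0.0626 to 0.213). The B2m call with LPS ended when any single KO_con, WT_M1 or KO_M1 library was left out (adjusted p = 0.0551 to 0.126) and under those 3 scalings at -0.25, -0.05 and -0.23 (adjusted p = 0.197 to 0.667). Without LPS B2m passed without WT_con 1 at -0.52 (adjusted p = 0.0280) and with voom (adjusted p = 0.0146), and was -0.11 without WT_con 2. Tbp passed in no comparison as deposited, and its LPS change in WT of 0.14 ± 0.10 turned to -0.27 and -0.20 under TPM and total-read scaling. Its LPS change in KO of -0.04 ± 0.10 became -0.45 and -0.30 under those scalings and passed (adjusted p = 0.0236 and 0.0241), and was 0.04 under quantile normalization. Gapdh, read at 1.28 ± 0.518 FPKM in WT_con, rose with LPS by 0.50 ± 0.15 (adjusted p = 0.0234) in WT. That call ended without WT_con 2, WT_M1 1 or WT_M1 2 (adjusted p = 0.0661 to 0.0838) and under TPM and total-read scaling (adjusted p = 0.532 and 0.568), and the change was 0.26 without WT_con 2. In KO its change was 0.28 ± 0.15 (adjusted p = 0.145), which did not pass. The group means of Gapdh were 1.28 to 2.30 FPKM, against 993 to 4160 for Actb. Whether Gapdh lost reads to near-identical copies, as described below for mt-Nd3, was not examined.

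The first comparison asks what LPS does in WT macrophages. Nos2, the inducible nitric oxide synthase, rose by 10.06 ± 0.07 (adjusted p = 7.76e-10), from 0.0313 ± 0.0442 to 1103 ± 54.6 FPKM (n = 2 each). Cxcl10, an interferon-induced chemokine, rose by 9.85 ± 0.09 (adjusted p = 1.46e-09), and Acod1, which makes itaconate, rose by 9.53 ± 0.09 (adjusted p = 1.47e-09). The chemokine receptor Cxcr4 fell by 4.91 ± 0.05 (adjusted p = 1.65e-09), from 190.0 ± 4.26 to 5.35 ± 0.00635 FPKM, and the myeloid transcription factor Cebpa fell by 4.0 ± 0.05. Other large rises were in the collagenase Mmp13 (9.72 ± 0.05), the acute-phase gene Saa3 (9.70 ± 0.18), the antiviral genes Rsad2 (9.68 ± 0.09), Cmpk2 (8.70 ± 0.08), Ifit2 (8.59 ± 0.09), Isg15 (8.47 ± 0.22) and Mx1 (8.43 ± 0.07), the chemokine Ccl5 (9.34 ± 0.05) and Gbp5 (8.47 ± 0.05). Other large falls were in Arhgap19 (-5.40 ± 0.05), Zdhhc14, Tmem37, Enc1, the lysosomal sulfatase Sgsh, Rgs2, Tmem154, Slc26a11, Engase and St6gal1 (-3.95 ± 0.07).

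Among the lists, interferon-stimulated genes rose together in WT: of 49 tested, 49 rose, 0 fell and 0 did not pass (median 5.19, camera adjusted p = 7.01e-23), with Rsad2 and Cmpk2 as the largest. Of the 28 NF-kB regulators, 28 rose, 0 fell and 0 did not pass (median 3.02, camera adjusted p = 7.79e-13). The feedback inhibitor Socs3 (7.81 ± 0.10) and Traf1 (5.37 ± 0.05) were the largest changes. Of 26 antimicrobial and M1 effectors, 24 rose, 1 fell and 1 did not pass (median 5.06, camera adjusted p = 9.38e-11), led by Nos2 and Mmp13. Of 17 inflammatory cytokines, 16 rose, 1 fell and 0 did not pass (median 5.24, camera adjusted p = 1.43e-07). Il1rn (8.08 ± 0.05) and Il1a (7.84 ± 0.04) changed most. Despite its name, the cytokine list also holds the anti-inflammatory Il10 and the vasoconstrictor peptide gene Edn1. Of 17 chemokines, 15 rose, 2 fell and 0 did not pass (median 4.45, camera adjusted p = 8.00e-06), led by Cxcl10 and Ccl5. In MHC class I presentation, of 17 members 17 rose, 0 fell and 0 did not pass (median 3.07, camera adjusted p = 2.87e-08). The proteasome activator Psme2 (4.81 ± 0.14) and the transactivator Nlrc5 (4.59 ± 0.08) led the list. Of 17 inflammasome and pyroptosis genes, 16 rose, 1 fell and 0 did not pass (median 2.25, camera adjusted p = 4.76e-05). Il1b (7.07 ± 0.06) and Casp4 (4.96 ± 0.11) moved most. Of 24 apoptosis regulators, 17 rose, 5 fell and 2 did not pass (median 1.06, camera adjusted p = 0.00263), led by the survival genes Bcl2a1d (5.79 ± 0.09) and Bcl2a1a (5.67 ± 0.13). Each of these 8 lists had an adjusted p = 0.0821 with an estimated correlation.

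Metabolic lists moved in both directions. Of 22 glycolysis genes, 17 rose, 3 fell and 2 did not pass (median 1.11, camera adjusted p = 2.43e-04, adjusted p = 0.305 with an estimated correlation). The transporter Slc2a6 (5.76 ± 0.05) and Pfkfb3 (4.66 ± 0.04) rose most, and quantile normalization ended the list's call (adjusted p = 0.0623). Of 21 cholesterol synthesis genes, 2 rose, 11 fell and 8 did not pass (median -0.32, camera adjusted p = 0.0411, adjusted p = 0.306 with an estimated correlation). Dhcr7 (-1.98 ± 0.10) and Stard4 (-1.23 ± 0.08) were the largest changes. Of 30 lysosome and autophagy genes, 9 rose, 18 fell and 3 did not pass, or 9 and 19 adjusted over the list alone (median -0.28, camera adjusted p = 0.0411, adjusted p = 0.183 with an estimated correlation). Atp6v0d2 (-2.44 ± 0.08) and the protease Ctsd (-1.75 ± 0.05) changed most. Of 27 TLR4 signalling genes, 17 rose, 6 fell and 4 did not pass (median 0.53, camera adjusted p = 0.0468, adjusted p = 0.183 with an estimated correlation), with the adaptor Myd88 (2.90 ± 0.05) and Ikbke (2.58 ± 0.05), and the median turned to -0.02 and -0.05 under TPM and total-read scaling. Less the median of all genes it was 0.50 as deposited and 0.49 and 0.43 under those scalings. That call ended under TPM, total-read and quantile scaling (adjusted p = 0.0512 to 0.0825) and with an FPKM minimum of 5 (adjusted p = 0.245). It also ended without genes under 300 bases, without a trend and with replicate blocks (adjusted p = 0.0529 to 0.0615). The lysosome median less that of all genes was -0.32 as deposited and -0.94 under quantile normalization. Its call ended without a trend (adjusted p = 0.0649), with replicate blocks (adjusted p = 0.0518 and 0.0558) and without genes under 300 bases (adjusted p = 0.0543). For cholesterol synthesis an FPKM minimum of 5 (adjusted p = 0.0819), voom (adjusted p = 0.0573) and leaving out genes under 300 bases (adjusted p = 0.0537) ended the call. Of single libraries, the cholesterol call ended without WT_con 1 (adjusted p = 0.0509), the lysosome call without WT_M1 1, KO_M1 1 or KO_M1 2 (adjusted p = 0.0508 to 0.0526), and the TLR4 call when any single con or KO_M1 library was left out (adjusted p = 0.0524 to 0.0599). In all, limma called 8504 of 11887 genes, 4476 higher and 4028 lower, of which 2005 and 1232 changed by at least 1 on the log2 scale. The share of calls that were higher was 52.6%, and it was 25.7% under TPM, 25.3% under total-read scaling and 41.8% under quantile normalization.

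The same question was asked in the libraries labelled KO. Saa3 rose by 9.62 ± 0.18 (adjusted p = 2.43e-08), Ccl5 by 9.35 ± 0.05, Mmp13 by 9.04 ± 0.05 and Acod1 by 8.82 ± 0.09. Nos2 rose by 8.45 ± 0.07 (adjusted p = 2.01e-09), from 0.00512 ± 0.00724 to 351 ± 27.4 FPKM (n = 2 each), Rsad2 by 7.78 ± 0.09 and Cxcl10 by 7.59 ± 0.09. Ptges, a prostaglandin E synthase (7.98 ± 0.07), Il1b (7.67 ± 0.06), Il1rn (7.52 ± 0.05), Mx1 (7.42 ± 0.07) and Gbp2 (7.40 ± 0.06) completed the 12 largest rises. The largest falls were in Arhgap19 (-5.29 ± 0.05), Enc1 (-4.64 ± 0.08), Cxcr4 (-4.46 ± 0.05) and Rgs2 (-4.44 ± 0.11), followed by Tmem37, Tmem154, St6gal1, Slc26a11, Sgsh, Zdhhc14, Rassf3 and Slc46a3 (-3.87 ± 0.09).

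Interferon-stimulated genes rose in KO as well: of 49, 49 rose, 0 fell and 0 did not pass (median 4.58, camera adjusted p = 8.00e-25). Of 28 NF-kB regulators 27 rose, 0 fell and 1 did not pass (median 2.78, camera adjusted p = 6.87e-13), and of 26 antimicrobial and M1 effectors 24 rose, 1 fell and 1 did not pass (median 5.18, camera adjusted p = 4.87e-12). Of 17 MHC class I presentation genes 17 rose, 0 fell and 0 did not pass (median 2.77, camera adjusted p = 3.66e-09). Of 17 cytokines 16 rose, 1 fell and 0 did not pass (median 4.41, camera adjusted p = 7.24e-08), and of 17 chemokines 15 rose, 2 fell and 0 did not pass (median 3.44, camera adjusted p = 6.23e-06). Of 17 inflammasome genes 15 rose, 1 fell and 1 did not pass (median 1.27, camera adjusted p = 2.60e-05) and of 24 apoptosis regulators 16 rose, 4 fell and 4 did not pass (median 0.80, camera adjusted p = 0.00197). Each of these 8 lists had an adjusted p = 0.0769 with an estimated correlation. Of 22 glycolysis genes, 19 rose, 2 fell and 1 did not pass (median 1.36, camera adjusted p = 9.83e-07, adjusted p = 0.172 with an estimated correlation). Of 21 cholesterol synthesis genes, 2 rose, 13 fell and 6 did not pass (median -0.33, camera adjusted p = 0.00838, adjusted p = 0.215 with an estimated correlation), and of 30 lysosome and autophagy genes, 8 rose, 19 fell and 3 did not pass, or 9 and 19 adjusted over the list alone (median -0.31, camera adjusted p = 0.0158, adjusted p = 0.126 with an estimated correlation). The lysosome median less that of all genes was -0.32 as deposited and -0.90 under quantile normalization. On that scale glycolysis stood at 1.35 as deposited and 0.80 under quantile normalization, and apoptosis regulators at 0.79 and 0.40. Of 21 cell cycle genes, 3 rose, 15 fell and 3 did not pass (median -0.75, camera adjusted p = 0.00907, adjusted p = 0.115 with an estimated correlation), a call that ended under total-read scaling (adjusted p = 0.0671). Of 27 TLR4 signalling genes, 18 rose, 6 fell and 3 did not pass (median 0.60, camera adjusted p = 0.0229, adjusted p = 0.128 with an estimated correlation). An FPKM minimum of 5 ended the cell cycle and TLR4 calls (adjusted p = 0.153 and 0.158). In total 7828 genes passed by limma, 4123 higher and 3705 lower, of which 1602 and 1002 changed by at least 1. Calls that were higher made up 52.7%, and 26.3%, 26.4% and 42.0% under TPM, total-read and quantile scaling.

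KO against WT without LPS asks what the KO label goes with in unstimulated macrophages. F13a1, the A subunit of coagulation factor XIII, rose by 2.33 ± 0.06 (adjusted p = 3.31e-05), from 3.21 ± 0.112 to 20.2 ± 0.0639 FPKM (n = 2 each). Irf7, a transcription factor that drives interferon genes, fell by 1.5 ± 0.05 (adjusted p = 5.05e-05), from 12.3 ± 0.275 to 3.70 ± 0.152 FPKM. The protease Capn1 fell by 1.61 ± 0.08 (adjusted p = 4.30e-04), from 21.7 ± 2.09 to 6.41 ± 0.0604 FPKM. Mitochondrial entries also differed. The value of mt-Nd3, a subunit of respiratory complex I, rose by 3.03 ± 0.27 (adjusted p = 0.00258), while its near-identical nuclear copy Gm28438 went from 183 and 242 reads in WT_con to 43 and 35 in KO_con. The pair together changed by 0.22, so the mt-Nd3 value reflects how reads were split between them. The transfer RNA genes mt-Tg and mt-Tr had 0 reads in both WT_con libraries, 30 and 13 reads for mt-Tg in KO_con, and 13 and 12 for mt-Tr, a call that ended for mt-Tr when any single con library was left out (adjusted p = 0.0526 to 0.0889). Hpgd, which inactivates prostaglandins, rose by 1.38 ± 0.11, Gdf3 by 1.36 ± 0.09, Padi4 by 1.16 ± 0.08, the platelet chemokine Pf4 by 1.12 ± 0.14, the immediate early gene Egr1 by 1.10 ± 0.13, Lzts2 by 1.03 ± 0.10, the lectin Clec4n by 1.01 ± 0.10 and the neutrophil chemokine Cxcl2 by 1.01 ± 0.15. Other falls were in the glycosyltransferase Galnt12 (-2.27 ± 0.14), Pls3 (-1.81 ± 0.15), the cyclin-dependent kinase inhibitor Cdkn1c (-1.41 ± 0.10), Cd5l (-1.31 ± 0.08) and Ifi27l2a (-1.29 ± 0.14), followed by Ly9, Pbxip1, the scavenger receptor Colec12, Cd37 and Myo7a (-1.13 ± 0.07).

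Of 49 interferon-stimulated genes, 1 rose, 14 fell and 34 did not pass, or 2 and 20 adjusted over the list alone (median -0.14, camera adjusted p = 1.01e-07, adjusted p = 0.331 with an estimated correlation). Irf7 and Oas3 (-0.92 ± 0.06) fell most. Of 17 MHC class I presentation genes, 1 rose, 8 fell and 8 did not pass, or 2 and 13 adjusted over the list alone (median -0.27, camera adjusted p = 9.35e-06, adjusted p = 0.331 with an estimated correlation). H2-T23 fell by 0.69 ± 0.04 while Psme2 rose by 0.82 ± 0.14. Of 30 lysosome and autophagy genes, 0 rose, 4 fell and 26 did not pass, or 1 and 8 adjusted over the list alone (median -0.09, camera adjusted p = 0.00213, adjusted p = 0.331 with an estimated correlation). Atp6v0d2 (-0.46 ± 0.08) and Npc2 (-0.34 ± 0.07) fell, and TPM, quantile and total-read scaling ended the list's call (adjusted p = 0.0565 to 0.227). Of 17 inflammasome genes, 0 rose, 3 fell and 14 did not pass, or 0 and 6 adjusted over the list alone (median -0.08, camera adjusted p = 0.0358, adjusted p = 0.331 with an estimated correlation). Nlrc4 (-0.71 ± 0.06) and Il1b (-0.53 ± 0.06) fell, and the list's call ended under TPM and total-read scaling (adjusted p = 0.0565 and 0.0725). Of 18 alternative activation markers, 6 rose, 3 fell and 9 did not pass, or 7 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 0.0180, adjusted p = 0.429 with an estimated correlation). The lectin Mgl2 rose (1.59 ± 0.14) and the folate receptor Folr2 fell (-0.99 ± 0.17), while TPM and total-read scaling ended the list's call (adjusted p = 0.0750 and 0.0806). Of 21 cholesterol synthesis genes, 0 rose, 0 fell and 21 did not pass (median 0.12, camera adjusted p = 0.0167, adjusted p = 0.331 with an estimated correlation). Mvd was 0.28 ± 0.06 and Lss 0.25 ± 0.12, and limma put 0 members past the threshold and 4 at an unadjusted p under 0.05. The list of monocyte markers passed with 1 member: of 7, 1 rose, 0 fell and 6 did not pass (median 0.12, camera adjusted p = 0.0424, adjusted p = 0.331 with an estimated correlation). F13a1 passed and Chil3 was 0.30 ± 0.18, and TPM, quantile and total-read scaling ended the call (adjusted p = 0.0541 to 0.152). So did no filter (median 0.05, adjusted p = 0.425), a pseudocount of 5 (median 0.04, adjusted p = 0.0712) and the replicate block (adjusted p = 0.0585). The list of mitochondrially encoded RNA, a sign of RNA quality, also passed with 1 member: of 15 entries, 1 rose, 0 fell and 14 did not pass (median 0.18, camera adjusted p = 0.0295, adjusted p = 0.544 with an estimated correlation). Of these mt-Nd3 passed, by the split of reads with Gm28438 and so not as a sign of RNA quality, mt-Atp8 was at -0.63 ± 0.35, and total-read scaling ended the call (adjusted p = 0.0831).

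Of 11887 genes limma called 671 in this comparison, 205 higher and 466 lower, with 25 and 42 of at least 1 on the log2 scale and 2549 at an unadjusted p under 0.05. Calls that were higher made up 30.6%, and 54.8%, 52.0% and 42.0% under TPM, total-read and quantile scaling. The count was 212 without WT_con 1, 144 without KO_con 1 and 155 without KO_con 2. Without WT_con 1, KO_con 1 or KO_con 2 the calls for Pf4, Cxcl2 and Psme2 ended (adjusted p = 0.0501 to 0.135), and without KO_con 2 those for Egr1 and Il1b did (adjusted p = 0.0568 and 0.0575). Cxcl2 stood at 0.55 with a pseudocount of 5 and did not pass (adjusted p = 0.0557), nor did it with no filter (adjusted p = 0.0517). When any single con library was left out those for Folr2, Atp6v0d2 and Npc2 ended (adjusted p = 0.0529 to 0.189), and without WT_M1 1 or WT_M1 2 that for Npc2 ended too (adjusted p = 0.0595 and 0.0596). Among the lists, without WT_con 2 the alternative activation and cholesterol calls ended (adjusted p = 0.102 and 0.103), and the inflammasome call ended without WT_con 2 or KO_con 1 (adjusted p = 0.0899 to 0.110). The monocyte call ended without WT_con 2, KO_con 2, KO_M1 1 or KO_M1 2 (adjusted p = 0.0569 to 0.136). The mitochondrial call ended without WT_con 1 or KO_con 1 (adjusted p = 0.216 to 0.539). Leaving out con libraries moved the medians to 0.15 to 0.38 for alternative activation (without WT_con 1, WT_con 2 or KO_con 1), 0.08 to 0.24 for monocytes (without WT_con 1, WT_con 2 or KO_con 2), 0.09 to 0.34 for mitochondrial RNA (any single con library left out) and -0.14 for the inflammasome (without KO_con 2).

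KO against WT with LPS asks the same after stimulation. Cxcl10 fell by 2.24 ± 0.09 (adjusted p = 6.10e-05), from 1133 ± 101 to 239 ± 4.94 FPKM (n = 2 each). The antiviral gene Rsad2 fell by 2.10 ± 0.09 (adjusted p = 6.73e-05), from 2587 ± 207 to 603 ± 69.1 FPKM. The monocyte chemokines Ccl7 and Ccl2 fell by 2.53 ± 0.22 (adjusted p = 3.97e-04) and fell by 2.08 ± 0.13 (adjusted p = 1.39e-04), and the vasoconstrictor peptide gene Edn1 fell by 2.06 ± 0.06 (adjusted p = 4.98e-05). The chemokine Ccl22 rose by 1.44 ± 0.12 (adjusted p = 3.00e-04). Other large falls were in Mid1 (-2.76 ± 0.11), Ifit1bl1 (-2.40 ± 0.10), Gbp4 (-2.20 ± 0.09) and the chemokine gene Cxcl11 (-2.12 ± 0.09). Cxcl11 is annotated as a polymorphic pseudogene. Pls3 (-2.09 ± 0.15), Aldh1b1 (-2.08 ± 0.07) and Cmpk2 (-2.02 ± 0.08) fell too. Other large rises were in Ifi208 (2.76 ± 0.10), mt-Nd3 (2.28 ± 0.27, or -0.37 summed with Gm28438), Apol7c (2.04 ± 0.10), Gdf3 (1.64 ± 0.09), the signalling adaptor Arrb1 (1.62 ± 0.07), Adam19 (1.61 ± 0.08) and Uchl1 (1.33 ± 0.16). For mt-Tg and mt-Tr both WT_M1 libraries had 0 reads, and KO_M1 had 8 and 20 reads for mt-Tg and 11 and 3 for mt-Tr. The microRNA genes Mir7663 (2.10 ± 0.58) and Mir7678 (1.75 ± 0.33) rose too, but the first call ended without WT_M1 1 or KO_M1 2 (adjusted p = 0.152 to 0.157) and the second without KO_M1 1 (adjusted p = 0.0501). With pseudocounts of 0.1 and 5 Mir7663 stood at 3.89 and 0.93 and did not pass (adjusted p = 0.0517 and 0.0570), nor did it with no filter, robust moderation or voom (adjusted p = 0.110, 0.0548 and 0.0885), and voom ended the Mir7678 call (adjusted p = 0.0591).

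**Figure D1:**
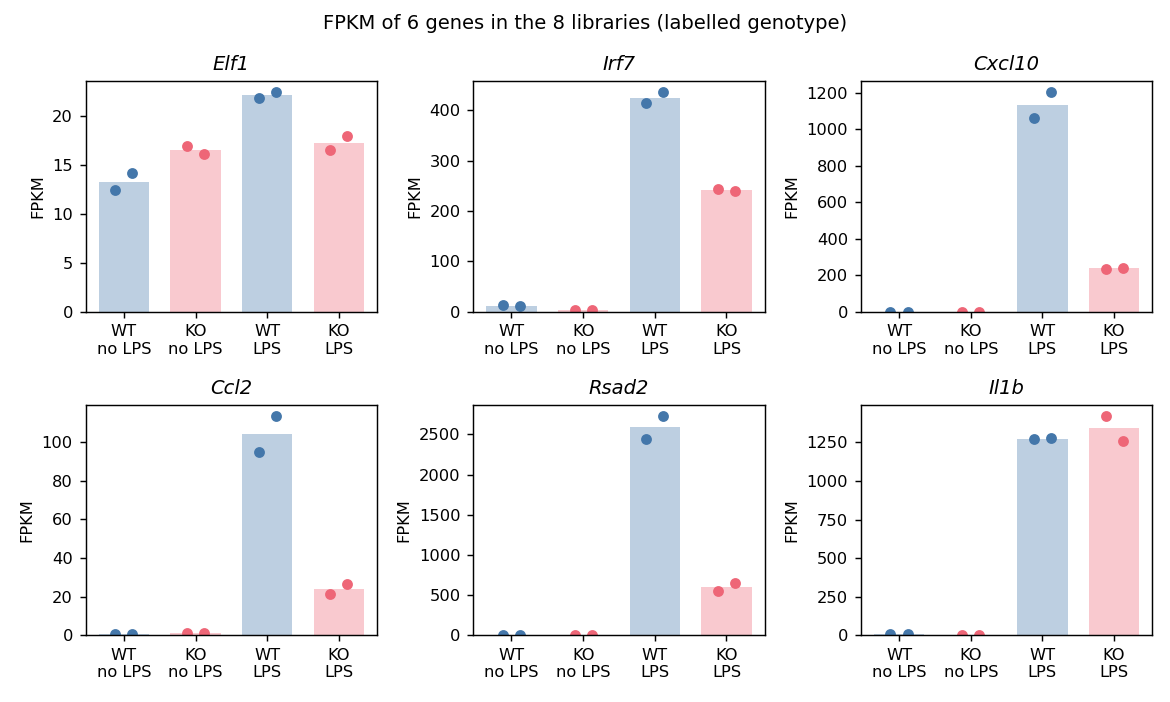
FPKM (linear axis) of Elf1, Irf7, Cxcl10, Ccl2, Rsad2 and Il1b in the 8 libraries, with points for libraries and bars for group means (n = 2). Cxcl10 stands at 1133 FPKM in WT_M1 and 239 in KO_M1, while Elf1 stands between 12.4 and 22.4 in every library.

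Interferon-stimulated genes were lower in KO throughout: of 49, 0 rose, 49 fell and 0 did not pass (median -0.81, camera adjusted p = 5.53e-27, adjusted p = 0.128 with an estimated correlation). Rsad2 and Cmpk2 fell most. Of 17 MHC class I presentation genes, 0 rose, 16 fell and 1 did not pass, or 0 and 17 adjusted over the list alone (median -0.60, camera adjusted p = 1.57e-09, adjusted p = 0.128 with an estimated correlation). Nlrc5 (-0.81 ± 0.08) and H2-T22 (-0.74 ± 0.05) led the list. Of 17 inflammatory cytokines, 0 rose, 12 fell and 5 did not pass (median -0.84, camera adjusted p = 5.73e-07, adjusted p = 0.148 with an estimated correlation). Edn1, which is on the list though not a cytokine gene, and Il15 (-1.59 ± 0.07) moved most. Of 17 chemokines, 3 rose, 10 fell and 4 did not pass, or 4 and 10 adjusted over the list alone (median -0.42, camera adjusted p = 0.0146, adjusted p = 0.194 with an estimated correlation). Ccl7 and Cxcl10 fell most. Of 28 NF-kB regulators, 1 rose, 19 fell and 8 did not pass, or 2 and 22 adjusted over the list alone (median -0.31, camera adjusted p = 2.15e-05, adjusted p = 0.286 with an estimated correlation). Atf3 (-0.99 ± 0.04) and Tnip3 (-0.67 ± 0.06) were the largest changes. Of 21 other pattern recognition receptors, 1 rose, 10 fell and 10 did not pass, or 1 and 13 adjusted over the list alone (median -0.22, camera adjusted p = 0.00639, adjusted p = 0.194 with an estimated correlation). The RNA sensor Tlr3 (-1.6 ± 0.08) and Tmem173, which encodes STING (-1.11 ± 0.15) changed most. Of 17 inflammasome and pyroptosis genes, 1 rose, 10 fell and 6 did not pass (median -0.37, camera adjusted p = 0.00819, adjusted p = 0.194 with an estimated correlation). The necroptosis effector Mlkl (-1.0 ± 0.18) and Il18 (-0.99 ± 0.17) led the list. Of 24 apoptosis regulators, 2 rose, 13 fell and 9 did not pass, or 2 and 14 adjusted over the list alone (median -0.27, camera adjusted p = 0.00819, adjusted p = 0.182 with an estimated correlation). Quantile normalization ended the calls for the NF-kB (adjusted p = 0.196), receptor (0.393), inflammasome (0.0526) and apoptosis lists (0.0574), and an FPKM minimum of 5 ended the chemokine and inflammasome calls (adjusted p = 0.0757 and 0.0522). The call for Mlkl ended under TPM scaling (adjusted p = 0.0509).

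Other groups were higher in KO with LPS. Of 18 genes of the NRF2 oxidative stress response, 12 rose, 0 fell and 6 did not pass, or 14 and 0 adjusted over the list alone (median 0.38, camera adjusted p = 3.48e-08, adjusted p = 0.128 with an estimated correlation), with Gclm, a subunit of the enzyme that begins glutathione synthesis (0.92 ± 0.08), and Osgin1 (0.75 ± 0.05). Of 9 MHC class II genes, 5 rose, 0 fell and 4 did not pass, or 5 and 1 adjusted over the list alone (median 0.40, camera adjusted p = 0.00410, adjusted p = 0.294 with an estimated correlation). H2-Aa (0.71 ± 0.06) and H2-Ab1 (0.63 ± 0.07) were the largest changes. Of 22 glycolysis genes, 11 rose, 5 fell and 6 did not pass, or 11 and 6 adjusted over the list alone (median 0.23, camera adjusted p = 0.0229, adjusted p = 0.574 with an estimated correlation). The lactate transporter Slc16a3 rose (0.88 ± 0.05) and the hexokinase Hk3 fell (-0.77 ± 0.05). That median was 0.37 without WT_con 1 or WT_con 2, and total-read scaling ended the call (adjusted p = 0.0671). The list of endothelial markers was lower too: of 5, 0 rose, 2 fell and 3 did not pass (median -0.27, camera adjusted p = 0.0298, adjusted p = 0.364 with an estimated correlation). Kdr (-1.51 ± 0.06) and Eng (-0.59 ± 0.10) fell, the latter not under quantile normalization (adjusted p = 0.0510), and the list's call ended without KO_M1 1 (adjusted p = 0.0607). In total limma called 3438 of 11887 genes, 1286 higher and 2152 lower, with 56 and 207 of at least 1 and 4850 at an unadjusted p under 0.05. Calls that were higher made up 37.4%, and 73.2%, 75.1% and 53.6% under TPM, total-read and quantile scaling. Less the median of all genes, the receptor median was -0.20 as deposited and -0.18, -0.15 and -0.03 under TPM, total-read and quantile scaling. On the same scale the NF-kB median was -0.29 as deposited and -0.25, -0.23 and -0.09, and the apoptosis median was -0.25 as deposited and -0.19, -0.16 and -0.15. The inflammasome median was -0.35 as deposited and -0.35, -0.30 and -0.33, so it hardly moved where its call ended. The MHC class I median was -0.57 as deposited and -0.54, -0.52 and -0.34. The count was 2084 without WT_M1 2.

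**Figure D2:**
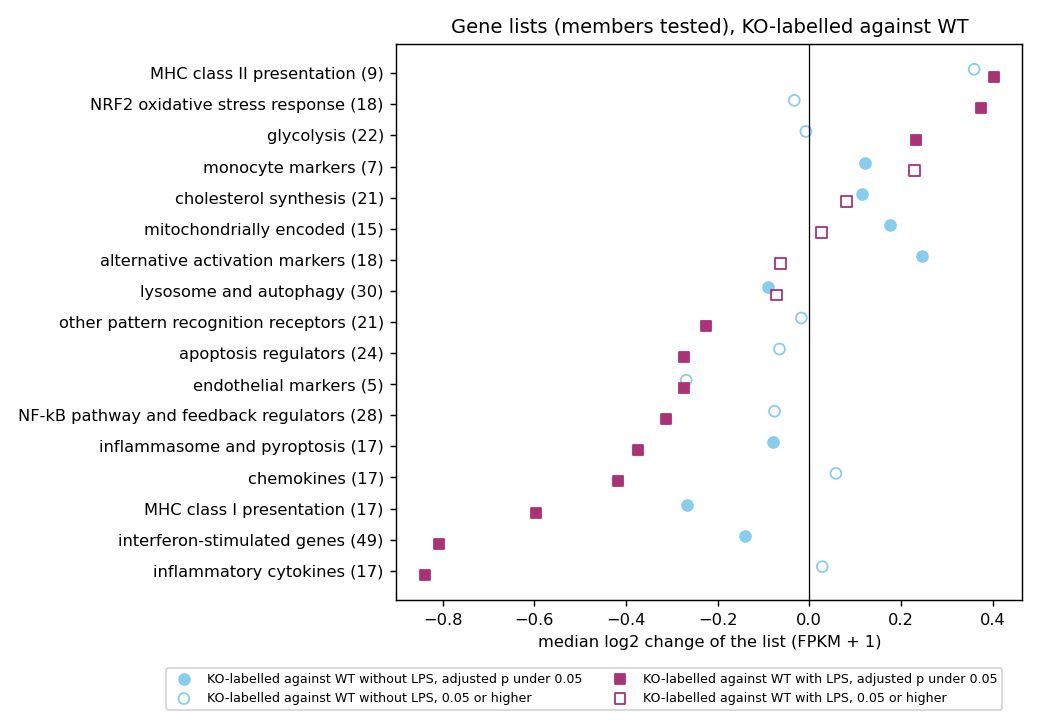
Median log2 change in KO against WT, without and with LPS, of each gene list that passed in either, with filled points for a camera adjusted p under 0.05. The interferon-stimulated list stands at -0.14 without LPS and -0.81 with it, and the NRF2 list at 0.38 with LPS.

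The interaction asks whether the LPS response differs between the labels. Ccl2 responded less in KO (-2.63 ± 0.18, adjusted p = 7.79e-04) and stood at 104 ± 13.3 FPKM in WT_M1 and 23.9 ± 3.86 in KO_M1 (n = 2 each). Cxcl10 (-2.27 ± 0.13, adjusted p = 6.99e-04) and the chemokine Ccl3 (-2.17 ± 0.11, adjusted p = 6.99e-04) also responded less, as did Tnfsf10, the death ligand TRAIL (-1.92 ± 0.12, adjusted p = 6.99e-04). Arrb1 (1.85 ± 0.10, adjusted p = 6.99e-04), the proteoglycan Sdc1 (1.26 ± 0.08, adjusted p = 7.14e-04) and the secreted matrix protein gene Tgfbi (1.14 ± 0.06, adjusted p = 6.99e-04) were more positive in KO. The other lowest values were in Ccl7 (-2.48 ± 0.31), Ifit1bl1 (-2.39 ± 0.14), Mid1 (-2.34 ± 0.15), Gbp4 (-2.18 ± 0.13), Cxcl11 (-2.12 ± 0.12), the GTPase Iigp1 (-2.07 ± 0.14), Mir222 (-2.02 ± 0.31) and Edn1 (-2.00 ± 0.09). The other highest were in Ifi208 (2.72 ± 0.15), Apol7c (2.06 ± 0.14), Galnt12 (1.69 ± 0.19, under 1 FPKM in both groups with LPS), Ccl22 (1.24 ± 0.16), Tsku (1.21 ± 0.18), Fgd3 (1.17 ± 0.10), Mthfd1l (1.17 ± 0.12), Stac2 (1.14 ± 0.12) and Slc43a2 (1.13 ± 0.07). With voom on the rebuilt reads the calls for Ccl7, Cxcl11, Edn1, Gbp4, Mir222, Ccl22 and Galnt12 ended, with an adjusted p of 0.0656 for Mir222 and 0.210 to 0.842 for the others. The values of Edn1, Gbp4, Ccl22 and Galnt12 were then -0.63, -0.73, 0.38 and 0.38. A pseudocount of 0.1 ended the calls for Ccl7 (adjusted p = 0.207), Ccl22 (0.217), Mir222 (0.0667) and Galnt12 (0.0817). Galnt12 was lower in KO at both stimulations, at 5.43 ± 0.833 and 0.325 ± 0.0124 FPKM without LPS and 0.547 ± 0.185 and 0.0292 ± 0.00112 with it, so its interaction depends on the pseudocount. Ifi208 and Tsku kept their calls, at 4.96 and 1.96 with a pseudocount of 0.1 and 1.13 and 0.50 with one of 5. TPM scaling ended those for Ccl7 (adjusted p = 0.132), Ccl22 (0.0521) and Mir222 (0.0565).

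Interferon-stimulated genes responded less in KO as a list: of 49, 3 were higher, 37 lower and 9 did not pass, or 3 and 40 adjusted over the list alone (median -0.72, camera adjusted p = 3.86e-15, adjusted p = 0.240 with an estimated correlation). Iigp1 and Ifit3b (-1.90 ± 0.16) were lowest. Of 17 cytokines, 1 was higher, 12 lower and 4 did not pass, or 1 and 13 adjusted over the list alone (median -0.83, camera adjusted p = 6.55e-08, adjusted p = 0.153 with an estimated correlation). Edn1 and Il15 (-1.68 ± 0.10) changed most. Of 17 chemokines, 3 were higher, 10 lower and 4 did not pass, or 3 and 11 adjusted over the list alone (median -1.03, camera adjusted p = 5.52e-04, adjusted p = 0.153 with an estimated correlation). Ccl2 and Ccl7 were lowest. Of 18 NRF2 genes, 11 were higher, 0 lower and 7 did not pass, or 13 and 0 adjusted over the list alone (median 0.39, camera adjusted p = 5.80e-09, adjusted p = 0.153 with an estimated correlation). Srxn1 (1.13 ± 0.09) and the cystine transporter Slc7a11 (0.74 ± 0.09) led the list. Of 28 NF-kB regulators, 2 were higher, 12 lower and 14 did not pass, or 2 and 16 adjusted over the list alone (median -0.27, camera adjusted p = 9.53e-04, adjusted p = 0.464 with an estimated correlation). Atf3 (-0.98 ± 0.06) and Nfkbiz (-0.90 ± 0.11) moved most. Of 17 MHC class I genes, 0 were higher, 10 lower and 7 did not pass, or 1 and 12 adjusted over the list alone (median -0.36, camera adjusted p = 0.00143, adjusted p = 0.284 with an estimated correlation). Psme2 (-1.24 ± 0.20) and Nlrc5 (-1.15 ± 0.11) were the largest changes. Of 21 other pattern recognition receptors, 0 were higher, 8 lower and 13 did not pass, or 0 and 9 adjusted over the list alone (median -0.25, camera adjusted p = 0.00634, adjusted p = 0.284 with an estimated correlation). Tlr3 (-1.29 ± 0.12) and Tlr7 (-1.26 ± 0.08) changed most. Quantile normalization ended the NF-kB (adjusted p = 0.537), MHC class I (0.559) and receptor calls (0.0842). Of 11887 genes limma called 1900, 671 higher and 1229 lower, with 46 and 189 of at least 1 and 3579 at an unadjusted p under 0.05. Calls that were higher made up 35.3%, and 57.4%, 63.8% and 51.8% under TPM, total-read and quantile scaling. The count was 967 without KO_con 1, 981 without KO_con 2, 1260 without WT_M1 1 and 1039 without WT_M1 2.

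Across genes, which are not independent replicates, the LPS changes in WT and KO had a Pearson correlation of 0.949. Over the 2831 genes whose average LPS change passed and was at least 1 in size, the slope of KO on WT was 0.872 in a fit with an intercept. Fits through the origin gave 0.861 for induced genes and 0.895 for lowered ones. Among 1758 induced genes the interaction was lower for 672 and higher for 90, with a median of -0.28. Among 1073 lowered genes it was higher for 195 and lower for 33, with a median of 0.15. LPS called 3727 genes higher and 3271 lower under both labels, and 59 in opposite directions. The KO against WT changes without and with LPS had a correlation of 0.234 across genes. In both, 75 genes were called higher and 248 lower, where independent calls would give 22.2 and 84.4, and 78 were called in opposite directions. Both comparisons used the same estimate of spread per gene, so calls can coincide more often than that without a shared effect. No value for independent calls was computed for the opposite directions.

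**Figure D3:**
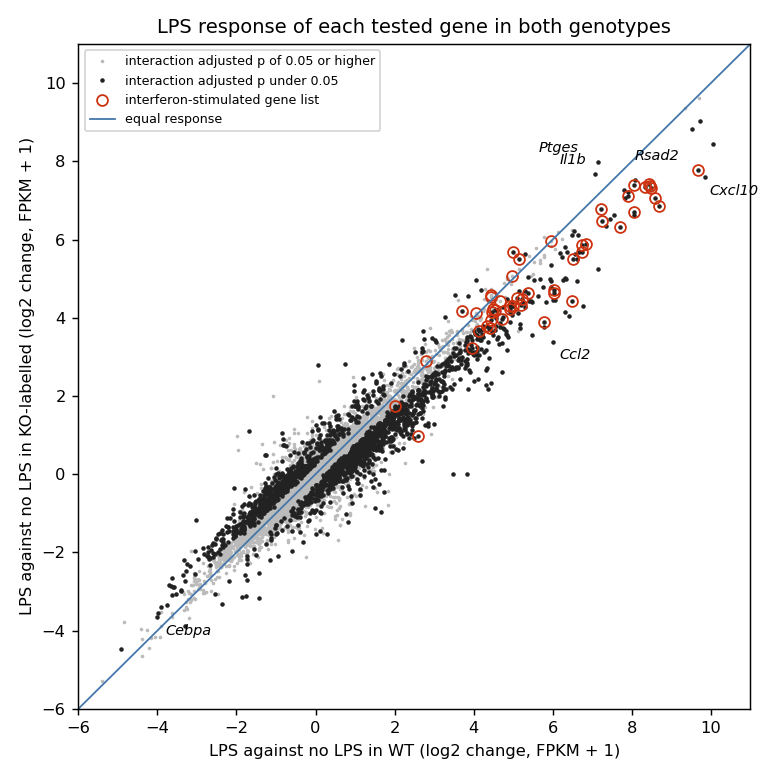
LPS log2 change of each tested gene in WT (horizontal) and KO (vertical), with black points for an interaction adjusted p under 0.05, red circles for the interferon-stimulated list, and a line of equal response. The slope over strongly changed genes is 0.872, and the red circles lie mostly under the line, with a median interaction of -0.72.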

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

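The values in the next paragraph are given because the LPS response differed between the KO and WT libraries by the interaction test itself. The level of Elf1, the genes called alike in KO against WT without and with LPS, and the mitochondrial reads were not selected by that test. Of the tests below, those of labels and transcript at Elf1, of the interferon-stimulated list, of the mitochondrial genome and of clustering against genes called with LPS alone were chosen only after the result was seen.

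The interaction of Elf1 was -0.64. Chemokine genes had interactions of -2.63 (Ccl2), -2.48 (Ccl7), -2.27 (Cxcl10), -2.17 (Ccl3), -2.12 (Cxcl11), -1.03 (Cxcl2) and 1.24 (Ccl22), with a list median of -1.03. An interaction can stem from the level without LPS. Cxcl2 stood at 2.44 FPKM in WT_con and 5.92 in KO_con, but at 214 in WT_M1 and 211 in KO_M1. Genes of the cytokine list had -2.00 (Edn1), -1.68 (Il15), -1.12 (Il18), -1.11 (Tnf), -0.94 (Il10), -0.83 (Il6), -0.78 (Il1a), -0.56 (Il1rn) and 0.60 (Il1b), with a list median of -0.83. Tnfsf10, which is not on that list, had -1.92. Interferon-responsive genes had -2.39 (Ifit1bl1), -2.18 (Gbp4), -2.07 (Iigp1), -1.90 (Ifit3b), -1.89 (Rsad2), -1.83 (Cmpk2), -1.51 (Ifit2), -1.15 (Gbp5), -1.01 (Mx1), -0.65 (Gbp2), 0.49 (Oas3), 0.69 (Irf7), 0.81 (Ifi27l2a) and 2.72 (Ifi208), with a list median of -0.72. Mean levels of Irf7 in WT and KO were 12.3 and 3.70 FPKM without LPS and 425 and 242 with it. Those of Ifi27l2a were 34.6 and 13.6 without and 101 and 72.2 with LPS, so both stood lower in KO at both stimulations. Genes of the NF-kB list had -0.98 (Atf3), -0.90 (Nfkbiz), -0.88 (Tnip3), -0.55 (Socs3) and -0.33 (Traf1), with a list median of -0.27. Receptor genes had -1.29 (Tlr3) and -1.26 (Tlr7), with a list median of -0.25 for other pattern recognition receptors. MHC class I genes had -1.24 (Psme2), -1.15 (Nlrc5) and -0.36 (H2-T22), with a list median of -0.36. NRF2 genes had 1.13 (Srxn1), 0.74 (Slc7a11), 0.70 (Gclm) and 0.51 (Osgin1), with a list median of 0.39. The inflammasome gene Casp4 had -0.88. Metabolic genes had -0.99 (Slc2a6), -0.80 (Pfkfb3), -0.46 (Hk3), 0.72 (Ldha), 0.84 (Tpi1), 0.97 (Slc16a3), 1.17 (Mthfd1l), -1.06 (Aldh1b1) and -1.73 (Hpgd). Effector genes had -1.61 (Nos2), -0.71 (Acod1), -0.69 (Mmp13) and 0.83 (Ptges). Surface and identity genes had -0.81 (Mertk), -0.81 (Mrc1), -0.99 (Kdr), 0.35 (Csf1r), 0.69 (Cx3cr1), 0.45 (Cxcr4), 0.46 (Cd37) and 1.26 (Sdc1). Transcription factor genes had 0.67 (Elk3), 0.54 (Fli1), 0.34 (Cebpa) and -1.34 (Egr1). Other genes had -2.34 (Mid1), -2.02 (Mir222), -1.63 (F13a1), -1.59 (Pf4), -0.57 (Slc46a3), 0.44 (Myo7a), 0.45 (Engase), 0.78 (Pbxip1), 0.89 (Cdkn1c), 0.90 (Uchl1), 1.13 (Slc43a2), 1.14 (Stac2), 1.14 (Tgfbi), 1.17 (Fgd3), 1.21 (Tsku), 1.69 (Galnt12), 1.85 (Arrb1) and 2.06 (Apol7c). F13a1 stood higher in KO at both stimulations, at 3.21 FPKM in WT_con, 20.2 in KO_con, 10.9 in WT_M1 and 18.4 in KO_M1. With voom Galnt12, Ccl22, Gbp4 and Edn1 stood at 0.38, 0.38, -0.73 and -0.63 and did not pass (adjusted p = 0.730 to 0.842). The calls for Il6 and Il10 ended with voom (adjusted p = 0.988 and 0.381) and under TPM (0.0566 and 0.0944), and that for Cx3cr1 ended with a pseudocount of 5 (0.879). Those for Csf1r ended without KO_con 1, WT_M1 1 or WT_M1 2 (adjusted p = 0.0507 to 0.0638), for Cx3cr1 without KO_con 1 (0.0662), and for Fli1 without WT_con 2, KO_con 1, KO_con 2, WT_M1 1, KO_M1 1 or KO_M1 2 (0.0602 to 0.108).

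Elf1 was not depleted in the libraries labelled KO: the lowest of the 8 libraries held 55.2% of the highest, so no library was depleted either way. For that reason an exchange of all WT with all KO labels cannot be told apart from correct labels as long as the allele leaves a counted transcript. For an exchange of only some labels, the share of reads taken by mt-Nd3, described below, was compared. That share was at least 72.1 percentage points higher in each of the 4 KO libraries than in any of the 4 WT libraries. However, mt-Nd3 was named by a rule that asks for libraries that do not overlap between the labels. The share is also no measure of the Elf1 allele. It speaks against such an exchange only if maternal lineage goes with genotype, which is not known here. The KO against WT changes of Elf1 went both ways, 0.296 without LPS and -0.35 with it, and totals per gene do not show exons, so a deletion that leaves a counted transcript and an intact gene cannot be told apart here. Genotype stays an open biological explanation for KO against WT differences other than that share.

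Interferon-stimulated genes were lower in the libraries labelled KO, with a list median of -0.72 in the interaction. A weaker LPS response of induced genes in general may account for it: 10000 random lists of genes induced alike had a median of -0.55 and a 95% range of -0.75 to -0.36, which placed the list at percentile 3.04, although such genes include others that respond to interferon. Under TPM, total-read and quantile scaling the list's KO against WT median with LPS was -0.61, -0.59 and -0.51, and -0.81 as deposited. Its interaction median was -0.53, -0.54 and -0.44 under those scalings. The medians stayed negative throughout, which argues against the authors' scaling as the whole cause, though their size depended on it. Less the median of all genes the list stood at -0.53 to -0.75 with LPS, and at -0.79 as deposited. TPM and total-read scaling shift all genes nearly alike and can hardly change that difference, which was -0.53 under quantile normalization. Trace LPS in the WT_con libraries cannot be told apart from a difference of this list without LPS: the 100 most induced other genes were at -0.0720 (bootstrap 95% interval -0.14 to -0.0020) and the 37 list members used at -0.15 (-0.24 to -0.09), so the intervals overlap. An effect of the genotype on interferon responses stays open.

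In KO against WT 323 genes were called in the same direction without and with LPS, 75 higher and 248 lower. Of these, 4 genes, or 1.24% (exact 95% interval 0.338 to 3.14%), lay within 10 Mb of Elf1, as did 61, or 0.513%, of all tested genes. So few tested genes lay there that the share had to be small whatever the cause. It therefore cannot decide how far variants carried along near Elf1 contribute. The set was clustered, as blocks of another strain's genome may produce. Genes whose symbols begin alike were not counted as neighbours of each other. The median distance to the nearest other member so counted was 1.06 Mb for 320 members. It was 1.70 Mb in random sets (percentile 0.1) and 1.71 Mb in sets of genes called in KO against WT with LPS alone. Without the interferon, MHC class I and MHC class II lists it was 1.37 Mb against 1.92 Mb (percentile 1.1). Neighbouring genes of 1 family with unlike symbols that move together would also do this. Reads also split differently between mt-Nd3 and its nuclear copy Gm28438, which differ at 1 of 345 bases: mt-Nd3 took 8.5 to 13.5% of the pair's reads in WT and 85.6 to 92.9% in KO, a gap of at least 72.6 percentage points within either stimulation, while the pair together changed by 0.22 without LPS and -0.37 with it. A candidate explanation is a mitochondrial genome that differs between the KO and WT lines, and so another strain or maternal lineage. The KO reads went mostly to mt-Nd3 itself, so the values do not place that difference in the KO line. By it the opposite calls for mt-Nd3 and Gm28438 may be of sequence and not of expression. The same may hold for mt-Tg and mt-Tr, which had 0 reads in every WT library. For the other genes of the set an effect of the genotype at Elf1 and one of background both stay open.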

How the results depend on the processing

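The alternatives with voom, total-read scaling, genes under 300 bases and list members on another list were chosen after seeing the data, and all others before. Counts stayed within 1.5 times the reported ones for LPS in WT, with 7712 to 8536 genes when each library was left out, and for LPS in KO, with 6741 to 7782. Of the values for genes and lists, 6410 kept their side of the threshold, 258 lost the call and 39 gained it. Of those called as reported, 0 were called in the opposite direction, while Elf1 for LPS in KO, not called at 0.06, was called at -0.29 to -0.41 under TPM, quantile and total-read scaling. Of 215 values called for named genes, a pseudocount of 0.1 made 18 larger and 1 smaller by over 1.5 times, a pseudocount of 5 made 60 smaller, and voom made 17 larger and 5 smaller. Scaling did so for 11 and 10 under TPM, 3 and 10 under total reads, and 6 and 12 under quantile normalization. KO against WT without LPS gave 406 genes with a replicate block, 1684 with voom and 327 with only the libraries compared, where fewer residual degrees of freedom are left, and 144 to 546 when each library was left out. With LPS that range was 2084 to 3469, and for the interaction 967 to 1753. A group left with 1 library was assumed to vary like the others. Lists passing numbered 0 in all 5 comparisons with an estimated correlation, against 12, 13, 8, 12 and 7 with the preset one, and 30, 29, 15, 22 and 15 by fry, which does not compare a list with other genes. For KO against WT without LPS they numbered 15 with voom, 4 with total-read scaling and 5 with only the libraries compared. For the interaction they numbered 11 without a filter, 11 under TPM, 11 with voom and 12 with total-read scaling, and 7 to 11 when each library was left out. The slope of the LPS responses was 0.904 under quantile normalization and 0.887 under total-read scaling, and the correlation of the KO against WT changes was 0.191 under TPM, 0.286 with voom, 0.275 without genes under 300 bases and 0.189 to 0.236 when each library was left out. The cause was not tested for these. Count models of other tools, planned for a table of raw counts alone, were not run on the rebuilt reads. At this depth a gene with 0 reads in a library can still stand at 0.190 CPM.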

Other observations

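No test in this part was run beyond the comparisons above, and the genes of its first paragraph other than list members fixed in advance were chosen after their values were seen.

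Among inflammatory genes, Tnf rose in KO without LPS by 0.44 ± 0.06 (adjusted p = 0.00780) and fell by 0.67 ± 0.06 (adjusted p = 3.25e-04) with LPS. The rise ended with only the libraries compared in the model (adjusted p = 0.0550). Il6 and Il10, a pro- and an anti-inflammatory cytokine, fell in KO with LPS (-0.84 ± 0.08 and -0.94 ± 0.07). Macrophage receptors differed by gene: the fractalkine receptor Cx3cr1 rose in KO by 0.86 ± 0.09 without and 1.56 ± 0.09 with LPS, the growth factor receptor Csf1r rose by 0.48 ± 0.05 with LPS, the Fc receptor Fcgr4 fell by 1.12 ± 0.08 without LPS and fell by 1.21 ± 0.08 with it, and the efferocytosis receptor Mertk fell by 0.84 ± 0.07 with LPS. The mannose receptor Mrc1 rose in KO without LPS by 0.72 ± 0.07 and was -0.08 ± 0.07 (adjusted p = 0.382) with it. The glycolytic enzymes Tpi1 and Ldha rose in KO with LPS by 0.66 ± 0.05 and 0.37 ± 0.05. Without LPS Tpi1 was -0.18 ± 0.05 (adjusted p = 0.0860), and Ldha fell by 0.36 ± 0.05 (adjusted p = 0.0164), a call that ended without WT_con 1, KO_con 1 or KO_con 2 (adjusted p = 0.0717 to 0.125). Of 15 ETS family genes, to which Elf1 belongs, 4 rose, 6 fell and 5 did not pass, or 4 and 8 adjusted over the list alone (median -0.18, camera adjusted p = 0.826) in KO against WT with LPS, with Elk3 (0.45 ± 0.07) and Fli1 (0.54 ± 0.09) rising. Without LPS 0 rose, 1 fell and 14 did not pass (median -0.04, camera adjusted p = 0.479).

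Of 30 macrophage identity genes, 1 rose, 7 fell and 22 did not pass, or 4 and 11 adjusted over the list alone in KO without LPS (median -0.08, camera adjusted p = 0.0624) and 5 rose, 11 fell and 14 did not pass, or 5 and 13 adjusted over the list alone with LPS (median -0.11, camera adjusted p = 0.457). Fibroblast and stromal markers stood at a median of -0.91 without and -0.92 with LPS in KO, and limma put 0 of 6 past the threshold and 0 at an unadjusted p under 0.05 in either comparison (without LPS camera adjusted p = 0.0624; with LPS camera adjusted p = 0.453). Of the 33 lists tested, 20 passed camera in at least 1 comparison and 13 in none, with a lowest adjusted p of 0.0571 among the 13, for immediate early and stress genes in the interaction. Another 8 lists had under 5 tested members. Of the 10 type I and III interferon genes on the list, which leaves out other members of the family, Ifnb1 alone had reads, 3 and 3 in WT_M1 and 3 and 0 in KO_M1, too few to show a difference at this depth.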
